A study of Salmo salar with 2 samples.

How the data were processed

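Single-nucleus RNA sequencing was applied to livers of Atlantic salmon whose embryos had been kept at 4, 6 or 8 °C until they reached the eyed stage, and which were collected a month after first feeding. Per the labels' protocols, livers were minced in a detergent buffer, nuclei were strained, fixed and barcoded with the Parse Evercode WT v2 Mini kit, which marks nuclei by rounds of split pooling in place of droplets, and the pooled libraries were run on an Illumina NextSeq flow cell. The series holds 2 sequencing libraries, each with nuclei of all livers, and count tables for 6 sample codes, 2 per temperature. Each code was read as temperature, number and tissue, so that the first digit gave the incubation temperature; this reading rests on the codes and the series design together, because no label states it per sample. The second digit, 4 or 5, is used here only as a name (4 °C liver 4, 4 °C liver 5 and so on), since its meaning is not given in the sources used here. Whether a code stands for 1 fish or for pooled fish is not given either, so p-values measure only the spread between these samples.

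The deposited values are raw counts of transcripts, counted by unique molecular identifiers (UMIs), per nucleus and gene, per the file headers; every value was a whole number, and in every nucleus the counts summed to the transcript total of the deposited nucleus table. Per the submitters' processing notes, STARsolo was used upstream; its version, the genome build and the annotation are not given in the sources used here. The deposited nucleus tables also hold other per-nucleus values, the number of genes with a transcript and the number of mapped reads, of which the gene numbers matched the count tables; the mapped reads were not used. The gene tables list 69389 identifiers, of which 30458 carry a name other than the identifier. The RefSeq gene table of assembly Ssal_v3.1 shares no identifier with them, so gene names are those of the deposited tables, and at most 2 loci without a symbol are given per direction in each comparison. Salmon keep many duplicated genes. Copies are counted as separate loci under their own identifiers, and reads from near-identical copies could have been split or shared between them, so a difference between copies of 1 symbol is uncertain. No mitochondrial gene could be told by name, so the planned upper limit of 5% mitochondrial UMIs was not applied.

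Nuclei with at least 200 detected genes were kept (scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Doublet scores came from Scrublet as run through scanpy, per liver, with 5% expected doublets. Its automatic thresholds marked 1015 nuclei, 987 of them in 6 °C liver 4 and at most 16 in any other liver, so the 5% of nuclei with the highest scores in each liver were removed instead; this rule was set after the data were seen. Of 16864 nuclei, 2 had too few genes, 842 were removed as doublets and 16020 were kept. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes and 30 principal components (scikit-learn 1.9.0) were used for a graph of 15 nearest neighbours, and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9) gave 12 clusters with no integration of livers. Clusters were named from marker lists for hepatocyte, cholangiocyte, endothelial, mesenchymal, erythroid, thrombocyte, immune, pancreatic, intestinal epithelial and adipocyte cells. Each list was scored per cluster as the mean over its loci of log2 of the mean scaled count plus 0.05, rescaled from 0 to 1 between the lowest and the highest cluster, over loci that spanned at least 1 on the log2 scale. The highest-scoring list with at least 3 markers detected in 5% or more of the nuclei named the cluster, and hepatocyte clusters with a cell cycle score above 0.5 were set apart as cycling hepatocyte-like. The markers were fixed before the data were examined, the scoring rule afterwards.

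Counts were summed per liver and class, since nuclei are not replicates, and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by temperature, and the quasi-likelihood test in 1 fit of all 6 livers, so that 3 residual degrees of freedom were shared by the comparisons. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The SE of a log2 fold change was derived as its absolute value divided by the square root of the quasi-likelihood F statistic. It is not the spread between livers. Other classes were tested at 8 against 4 °C where every liver gave at least 20 nuclei. Gene lists were tested with camera (limma 3.58.1) on voom log2 CPM (counts scaled to a common total) with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, a rotation test that does not compare a list with other genes. Of the lists fixed before the data were examined, 29 had the 5 loci required. They covered carbohydrate, lipid, cholesterol, amino acid and bile acid metabolism, respiration, lipid transport, plasma proteins, antiviral and stress responses, protein synthesis and breakdown, hormone and nuclear receptor signalling, the clock, chromatin, the cell cycle, iron and hypoxia; a list for vitellogenesis had 1 tested locus and was not tested. A symbol stood for every locus that bears it alone or with a copy suffix, and names for which the suffix made another gene were taken out by hand after the data were seen. For each list the number of loci that passed is given over all genes and adjusted over the list alone, and the number of loci in which both livers of 1 temperature lay above both of the other is set beside chance, 16.7% per direction. This chance holds for 1 locus with exchangeable livers. Loci of a list share the same livers and can move together, so these counts are not a test. Some single genes that were tested are not reported here.

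Genes are named by a rule fixed before the data were examined: genes that passed with non-overlapping livers, a symbol and a mean of at least 5 CPM, up to the 8 largest rises and falls; up to 4 members with the smallest p of each list that passed or that holds a gene that passed; and up to 5 genes per direction in other classes. Levels per liver are CPM over the summed counts with TMM scaling. CPM of cell type markers, and of single genes within cluster 1 alone, are without it. Mean list levels with TMM scaling are edgeR log2 CPM with a prior count of 2. Those without TMM scaling are log2 of CPM with a pseudocount of 0.5 CPM. Shares of nuclei carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Shares, and UMIs and genes per nucleus, were tested by the slope on temperature. The test was two-sided and exact, over the 90 distinct arrangements of 6 livers in 3 pairs. The smallest p this test can give is 0.0222. With only 1 class at this p, Benjamini-Hochberg adjustment over 8 classes gives 0.178, so no share could pass alone. Genes per nucleus were also compared with each nucleus thinned to 2000 UMIs. Groups of 2 leave too few other splits of the samples for a test. For any difference among temperatures, genes were also counted over the other ways to put the 6 livers in 3 pairs.

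The tests were tested on simulated data with known answers. For the comparison of 8 with 4 °C over 25823 simulated genes tested, edgeR recovered 33% of genes changed by a fold of 2 and 96% of those changed by a fold of 4, with 9 unchanged genes called, and DESeq2 1.42.0 recovered 50% and 95% with 19 unchanged genes called. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery at lower levels was not measured. A simulated list of 30 loci moved by 0.7 on the log2 scale passed camera with the preset correlation (adjusted p = 3.05e-20) and with an estimated correlation (adjusted p = 0.0482). It also passed in fry (adjusted p = 0.00524), each on the same 25823 simulated genes and for the same comparison. No unchanged list of the 28 passed. Simulated genes were drawn independently of each other. Lists whose genes move together, such as cholesterol synthesis (estimated correlation 0.234 at 8 against 4 °C), were not simulated, so false calls of such lists were not measured. Alternatives fixed before the data were examined were DESeq2, its size factors within edgeR, no filter and a stricter filter on low counts (10 CPM in 2 livers), the number in the code as a block, temperature as a straight line, only the 4 livers compared, at least 400 genes per nucleus, no doublet removal, all nuclei summed, Leiden resolution 1.0, each sequencing library alone, thinned sums, limma-voom, and leaving out each liver. Scrublet's automatic threshold and other choices of hepatocyte clusters were added afterwards. Figures were drawn with matplotlib 3.10.9. Reads were not analysed here.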

Results

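Nuclei were profiled from 6 Atlantic salmon livers, 2 for each embryonic incubation temperature of 4, 6 and 8 °C. All were collected at the same stage of early feeding. The comparison of temperatures asks which liver cells and transcripts still differ after the incubation treatment has ended. The 16864 deposited nuclei carried 156459987 UMIs. Totals were 21034485 and 13617358 UMIs in the 4 °C livers, 52014359 and 20761568 in the 6 °C livers and 21888419 and 27143798 in the 8 °C livers. After filtering, 16020 nuclei remained, 1933 and 1681 at 4 °C, 4426 and 2573 at 6 °C, and 2909 and 2498 at 8 °C. Median UMIs per nucleus were 7500 and 5955 at 4 °C, 9023 and 6753 at 6 °C, and 5772 and 8714 at 8 °C. There was no trend beyond the spread between livers (slope 129 UMIs per °C, exact permutation p = 0.756). The slope turned to -101 without 4 °C liver 5 and to -122 without 8 °C liver 5. Median genes per nucleus ranged from 2785 to 3678 (exact permutation p = 0.844). Their slope also turned, to -41.8 and -60.1, without either of these livers. With every nucleus thinned to 2000 UMIs they lay between 1286 and 1326 (exact permutation p = 0.311). This left out 72 and 94 shallower nuclei at 4 °C, 72 and 149 at 6 °C, and 219 and 86 at 8 °C.

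Hepatocytes dominated the liver nuclei at every temperature. Hepatocyte-like nuclei, in which transferrin (tfa), tyrosine aminotransferase (tat) and plasminogen (plg) transcripts were detected in 99.0%, 98.9% and 99.6% of nuclei, numbered 11261. They made up 69.7% ± 2.47 (SD, n = 2) of nuclei at 4 °C, 74.1% ± 0.259 at 6 °C and 65.5% ± 0.591 at 8 °C. A cycling hepatocyte-like cluster of 1831 nuclei was led by the mitotic genes kif14 and cenpf. Smaller clusters were cholangiocyte-like (943 nuclei, led by afap1l1a and notch3, with anxa4 in 70.7% of nuclei), endothelial-like (480, led by oit3 and the VEGF receptor kdrl) and mesenchymal-like (462, led by the collagens col5a1 and COL6A3). Others were erythroid-like (581, led by DMTN and HBB1), immune-like (422, with the leukocyte integrin itgb2 among leading genes) and thrombocyte-like (40, led by f13a, thbs1b and itga2b). Markers of adipocytes, pancreatic endocrine cells and intestinal epithelium named no cluster. Hepatocyte transcripts also appeared in the other classes. tfa was detected in 46.8% of cholangiocyte-like nuclei (median 3781 UMIs) and 50% of endothelial-like nuclei (median 3747.5 UMIs), against 99.0% of hepatocyte-like nuclei (median 7373 UMIs).

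Endothelial-like nuclei were more frequent in livers from warmer incubation. Their share was 1.75% ± 0.642 (SD, n = 2) at 4 °C, 2.86% ± 0.464 at 6 °C and 4.12% ± 0.341 at 8 °C. The livers of the 3 temperatures did not overlap. They were 1.29% (exact 95% interval 0.839 to 1.90) and 2.20% (1.55 to 3.02) at 4 °C, 2.53% (2.09 to 3.04) and 3.19% (2.54 to 3.94) at 6 °C, and 4.37% (3.65 to 5.17) and 3.88% (3.16 to 4.72) at 8 °C. The slope was 0.594 percentage points per °C. Its exact permutation p was 0.0222, the smallest that 90 arrangements can give, and 0.178 after adjustment over 8 classes, so the trend did not pass. An edgeR test on numbers of nuclei gave a slope of 0.31 on the log2 scale per °C (edgeR adjusted p = 0.0356, against 0.178 in the exact test under the other alternatives and 0.267 to 0.533 with 1 liver left out). Erythroid-like nuclei went the other way, from 5.19% ± 1.92 (SD, n = 2) at 4 °C to 2.74% ± 1.04 at 8 °C (slope -0.612, exact permutation p = 0.111). Of these 581 nuclei, 83.5% fell among hepatocyte-like nuclei at the finer clustering, where the slope was -0.114. Cycling hepatocyte-like nuclei made up 11.3% ± 4.60 (SD, n = 2), 8.12% ± 0.716 and 15.6% ± 2.12 from 4 to 8 °C (slope 1.08, exact permutation p = 0.356). Slopes of the other shares were -1.05 for hepatocyte-like nuclei (exact permutation p = 0.333), 0.0860 for cholangiocyte-like (p = 0.933), -0.137 for immune-like (p = 0.378), 0.00301 for mesenchymal-like (p = 1) and 0.0374 for thrombocyte-like nuclei (p = 0.222). All were two-sided exact tests. Leaving out 4 °C liver 4 turned the cholangiocyte-like slope to -0.383 and the mesenchymal-like slope to -0.156. Leaving out 8 °C liver 4 turned the latter to -0.231.

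**Figure D1:**
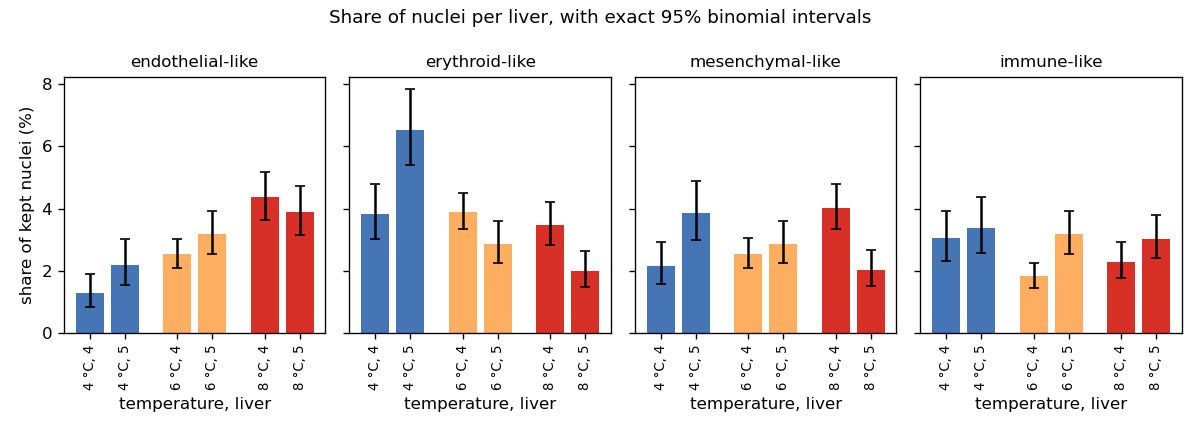
Share of kept nuclei (%) in 4 cell classes, 1 bar per liver with its exact 95% binomial interval, coloured by embryonic temperature. Endothelial-like shares run from 1.29% and 2.20% in the 4 °C livers to 4.37% and 3.88% in the 8 °C livers with no overlap between the 3 temperatures.

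The hepatocyte-like class drew on 4 clusters in proportions that differed between livers. Values within it are therefore read beside its make-up, which is not itself a comparison because the clusters are defined by genes that differ between livers. Cluster 1, led by xirp2a and PIPOX, held 53.3% and 42.3% of hepatocyte-like nuclei at 4 °C, 11.4% and 31.2% at 6 °C, and 75.4% and 63.7% at 8 °C. Cluster 2, led by the lipogenic genes fasn, elovl6 and acaca, held 57.2% in 6 °C liver 4 and 14.6% to 21.6% in the other livers. Cluster 3, led by pnp5a and IGFBP1, held 30.5% and 44.3% at 6 °C, 21.5% in 8 °C liver 5 and 3.26% to 6.39% in the remaining livers. Cluster 5, led by lpin1, ghrb and dio2, held 28.1% and 29.7% at 4 °C and at most 5.99% elsewhere. Summed hepatocyte-like counts were 12215078 and 7686777 UMIs at 4 °C, 33272133 and 14091587 at 6 °C, and 11948342 and 15378447 at 8 °C. Endothelial markers in these sums were at 45.3 and 49.7 CPM at 4 °C and at 44.7 and 39.5 at 8 °C. Mesenchymal markers were also lower at 8 °C (58.8 and 57.2 CPM at 4 °C, 52.1 and 51.3 at 8 °C). Cholangiocyte markers (273 and 264 at 4 °C, 293 and 325 at 8 °C) and hepatocyte markers (16866 and 18558, 19295 and 20407) went the other way.

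The comparison of 8 with 4 °C livers asked which hepatocyte transcripts differ over the full temperature range. Transcripts of cholesterol synthesis were higher at 8 °C, where cluster 1 held most hepatocyte-like nuclei and cluster 5 few. Of the list, 28 of 30 loci lay above 0, with a median log2 fold change of 0.72. hmgcs1, which makes the precursor of mevalonate, stood at 374 ± 37.4 CPM (SD, n = 2) at 4 °C and 678 ± 103 at 8 °C (log2 fold change 0.86, SE 0.16, edgeR adjusted p = 0.243). The later pathway enzymes msmo1 and mvk had log2 fold changes of 0.75 (SE 0.15) and 1.11 (SE 0.23). insig1, the sterol sensor that holds back the pathway, had 1.08 (SE 0.21), with edgeR adjusted p of 0.272 for msmo1, 0.33 for mvk and 0.272 for insig1. Both 8 °C livers lay above both 4 °C livers in 23 of the 30 loci, where chance gives 16.7% for 1 locus taken alone. The list passed camera (adjusted p = 8.56e-20), but not with an estimated correlation between its genes (adjusted p = 0.745 with an estimated correlation). Over the list alone 18 loci passed after adjustment, all higher, against 0 over all genes in edgeR, where 22 had an unadjusted p under 0.05. DESeq2, over all genes, called hmgcs1 (adjusted p = 0.00282), msmo1 (0.00681), insig1 (0.0111) and mvk (0.00628).

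Ribosomal protein transcripts were lower at 8 than at 4 °C, with 71 of 75 loci below 0 and a median log2 fold change of -0.46. rpl21 stood at 11.7 ± 1.80 CPM (SD, n = 2) at 4 °C and 5.17 ± 1.06 at 8 °C (log2 fold change -1.18, SE 0.24, edgeR adjusted p = 0.318). The others rplp1, rpl13a and RPL5 (ENSSSAG00000031075) had log2 fold changes of -1.09, -0.94 and -0.80. Both 8 °C livers lay below both 4 °C livers in 51 loci (chance 16.7%). The list passed camera (adjusted p = 2.00e-17; adjusted p = 0.745 with an estimated correlation). Adjusted over the list alone, edgeR called 0 loci, as over all genes, with 26 lower at an unadjusted p under 0.05. DESeq2 called rpl21 (adjusted p = 0.0470). Translation and ribosome biogenesis factors were lower in 28 of 36 loci (median -0.18), among them the cap-binding factor eif4eb (-0.61, SE 0.22), the scaffold EIF4G1 (-0.54), the initiation factor eif5 (-0.43) and the snoRNP protein nop56 (-0.62). Camera called this list (adjusted p = 0.00511; adjusted p = 0.854 with an estimated correlation), with both 8 °C livers below both 4 °C livers in 13 loci (chance 16.7%). Adjusted over the list alone edgeR called 0 loci, with 4 at an unadjusted p under 0.05. The call was lost without 4 °C liver 4 (adjusted p = 0.259), without 8 °C liver 5 (adjusted p = 0.292) and within cluster 1 alone (median -0.09, adjusted p = 0.114).

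Heat shock and chaperone transcripts lay below 0 in 26 of 36 loci at 8 against 4 °C (median -0.24), with members going both ways. The collagen chaperone serpinh1b was higher, at 20.5 ± 1.01 CPM (SD, n = 2) at 4 °C, 30.7 ± 1.02 at 6 °C and 38.5 ± 0.714 at 8 °C (log2 fold change 0.91, SE 0.15, edgeR adjusted p = 0.185, DESeq2 adjusted p = 0.00301). It was the 1 locus that passed adjusted over the list alone. The cold-inducible RNA-binding protein CIRBP was lower at both of its named loci (ENSSSAG00000087677, log2 fold change -0.59, SE 0.17; ENSSSAG00000000556, -0.45, SE 0.17), as was the mitochondrial co-chaperonin hspe1 (-1.73, SE 0.57), at 1.35 ± 0.124 CPM at 4 °C. Camera called the list (adjusted p = 0.0199; adjusted p = 0.860 with an estimated correlation), with both 8 °C livers below in 13 loci and above in 4 (chance 16.7% each). The call was lost without 4 °C liver 4 (adjusted p = 0.805), without 8 °C liver 5 (adjusted p = 0.292) and within cluster 1 alone (median -0.09, adjusted p = 0.217).

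Over all 26453 genes tested at 8 against 4 °C, 6 loci passed in edgeR, all higher and none with a symbol. At an unadjusted p under 0.05 there were 1881 genes, and DESeq2 called 106 (59 higher, 47 lower). The unnamed locus ENSSSAG00000085318 rose from 5.44 ± 2.35 CPM (SD, n = 2) at 4 °C to 79.0 ± 19.2 at 8 °C (log2 fold change 3.82, SE 0.35, edgeR adjusted p = 0.0280). ENSSSAG00000084894 rose from 177 ± 76.1 to 1274 ± 119 CPM (log2 fold change 2.84, SE 0.30, edgeR adjusted p = 0.0411). Without 4 °C liver 4, edgeR called 0 genes (1769 at an unadjusted p under 0.05; adjusted p = 0.0585 for both loci). Without 4 °C liver 5 it called 2 (adjusted p = 0.0978 for both loci), and without 8 °C liver 4 it called 17. In fry, which asks whether a list moves one way, the lowest adjusted p of any list was 0.307.

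**Figure D2:**
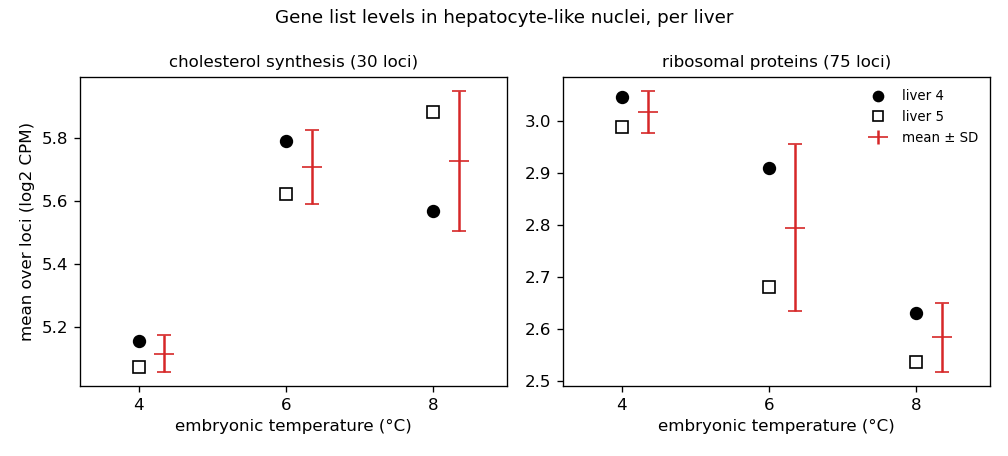
Mean level over the loci of 2 gene lists (log2 CPM) in hepatocyte-like nuclei against embryonic temperature (°C), 1 point per liver with the mean ± SD of each temperature. The cholesterol synthesis list lies at 5.16 and 5.07 in the 4 °C livers and at 5.57 or above in the others; the ribosomal protein list goes from 3.05 and 2.99 at 4 °C to 2.63 and 2.54 at 8 °C.

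The step from 4 to 6 °C showed the same direction for cholesterol synthesis, read against the same 4 °C livers, with more of cluster 3 in both 6 °C livers and of cluster 2 in 6 °C liver 4. At 6 °C 29 of 30 loci lay above 0 (median log2 fold change 0.64), and both 6 °C livers lay above both 4 °C livers in 24 (chance 16.7%). hmgcs1 reached 769 ± 54.4 CPM (SD, n = 2; log2 fold change 1.04, SE 0.16, edgeR adjusted p = 0.238). insig1 went from 14.0 ± 1.68 to 31.8 ± 0.811 CPM (1.17, SE 0.21), and the demethylase cyp51 and msmo1 had log2 fold changes of 0.82 and 0.67. Camera called the list (adjusted p = 6.90e-19; adjusted p = 0.490 with an estimated correlation). Within the list alone 16 loci passed after adjustment, all higher, against 0 over all genes in edgeR, where 19 had an unadjusted p under 0.05. DESeq2, over all genes, called hmgcs1 (adjusted p = 9.03e-05), insig1 (0.00295), cyp51 (0.00604) and msmo1 (0.0335).

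Antiviral response transcripts were lower at 6 than at 4 °C. The locus irf1-2, a copy of the transcription factor interferon regulatory factor 1, fell from 9.58 ± 2.84 CPM (SD, n = 2) to 0.997 ± 0.0607 (log2 fold change -3.26, SE 0.32, edgeR adjusted p = 0.0475) and stood at 2.10 ± 0.0142 at 8 °C. The locus irf1 was at 11.5 ± 6.06 CPM at 4 °C and 0.621 ± 0.487 at 6 °C (log2 fold change -4.41, SE 0.72, edgeR adjusted p = 0.264, DESeq2 adjusted p = 0.0226). The interferon signal transducer stat1a (ENSSSAG00000073567) and the RNA sensor tlr7 had log2 fold changes of -0.51 and -1.35. The livers overlapped for tlr7, at 4.47 and 1.51 CPM at 4 °C and 1.54 and 0.743 at 6 °C. Of the 12 loci of the list, 10 lay below 0 (median -0.37), and both 6 °C livers lay below in 5 (chance 16.7%). After adjustment over the list alone 2 passed, both lower, against 1 over all genes. Camera called the list (adjusted p = 1.43e-04; adjusted p = 0.490 with an estimated correlation). The call of irf1-2 was lost without any 1 of the 4 livers compared, with an adjusted p of 0.154 without 4 °C liver 4, 0.0909 without 4 °C liver 5, 0.322 without 6 °C liver 4 and 0.0644 without 6 °C liver 5.

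Glycogen metabolism, the TCA cycle, oxidative phosphorylation and lipid transport lay mostly higher at 6 than at 4 °C, while glycolysis (median log2 fold change -0.07) and fatty acid oxidation (-0.01) did not pass (camera adjusted p = 0.968 each). Glycogen metabolism lay above 0 in 18 of 23 loci (median log2 fold change 0.24), with the glycogen-targeting phosphatase subunits ppp1r3ca (0.96, SE 0.29) and ppp1r3b (0.61) and pgm1 (0.49). The TCA cycle lay above 0 in 39 of 46 loci (median 0.18), with the isocitrate dehydrogenases IDH3A (0.51, SE 0.18), idh2 (1.54, SE 0.60) and idh1 (0.40). Oxidative phosphorylation lay above 0 in 45 of 56 loci (median 0.22), with cox4i1 (0.45, SE 0.16), atp5mc3b (0.82) and cox5ab (ENSSSAG00000009477, 0.55) higher and NDUFS1 lower (-0.49). Lipoproteins and lipid transport lay above 0 in 22 of 33 loci (median 0.11), with APOH at 134 ± 23.3 CPM (SD, n = 2) and 209 ± 20.4, fabp3 (0.50), the LDL receptor ldlra (1.13, SE 0.44) and hepatic lipase lipca (0.57). Ribosomal proteins lay below 0 in 58 of 75 loci (median -0.20), with rps28 (-1.0), rpl21 (-0.68), rpl13 (-0.54) and faua (-0.85). Within cluster 1 alone the ribosomal median was -0.09 (camera adjusted p = 0.189).

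These 5 lists passed camera at 6 against 4 °C but not with an estimated correlation. For glycogen metabolism the adjusted p was 0.00587 (adjusted p = 0.584 with an estimated correlation), for the TCA cycle 0.00116 (0.584), for oxidative phosphorylation 9.25e-04 (0.669), for lipoproteins 0.0224 (0.515) and for ribosomal proteins 5.28e-05 (0.728). Both 6 °C livers lay above both 4 °C livers in 10, 20, 20 and 12 loci of the first 4 lists, and below in 32 ribosomal loci (chance 16.7%). Adjusted over the list alone edgeR called 0 loci in each, as over all genes, with 3, 2, 2 and 5 higher and 8 ribosomal loci lower at an unadjusted p under 0.05. DESeq2 called none of the named members. Without 6 °C liver 4 the adjusted p was 0.331 for glycogen metabolism, 0.209 for oxidative phosphorylation and 0.321 for the TCA cycle, which was also lost without 4 °C liver 4 (0.0577). The lipoprotein call was lost without 4 °C liver 4 (0.0925), 4 °C liver 5 (0.0754), 6 °C liver 4 (0.0512) or 6 °C liver 5 (0.179). The ribosomal call was lost without 6 °C liver 5 (0.0725). Within cluster 1 alone the glycogen (median 0.09, adjusted p = 0.467) and TCA cycle calls (0.10, adjusted p = 0.101) were lost too.

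Over all genes at 6 against 4 °C, edgeR called 2 of 26453, irf1-2, lower, and the unnamed locus ENSSSAG00000122006. The latter rose from 42.0 ± 4.47 CPM (SD, n = 2) to 146 ± 21.5 (log2 fold change 1.79, SE 0.17, edgeR adjusted p = 0.0475) and stood at 20.4 ± 1.59 at 8 °C. At an unadjusted p under 0.05 there were 1742 genes, and DESeq2 called 95 (65 higher, 30 lower). The edgeR count was 0 without 4 °C liver 4 (1708 unadjusted) and without 6 °C liver 4 (1470 unadjusted), 6 without 4 °C liver 5, 4 without 6 °C liver 5, 13 without 8 °C liver 4 and 12 without 8 °C liver 5. ENSSSAG00000122006 was lost without 4 °C liver 4 (adjusted p = 0.228), 4 °C liver 5 (0.196), 6 °C liver 4 (0.0624) or 6 °C liver 5 (0.0587). The lowest adjusted p in fry was 0.0890.

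From 6 to 8 °C, with more of cluster 1 and less of cluster 3, transcripts of oxidative phosphorylation, the TCA cycle and amino acid breakdown were lower. Oxidative phosphorylation lay below 0 in 49 of 56 loci (median log2 fold change -0.28), with both 8 °C livers below both 6 °C livers in 27. ndufa8 went from 38.4 ± 3.05 CPM (SD, n = 2) to 26.7 ± 2.42 (log2 fold change -0.53, SE 0.16, edgeR adjusted p = 0.583). The subunits atp5mc3b, cox5ab (here ENSSSAG00000073175) and cox4i1 had log2 fold changes of -1.14, -0.83 and -0.50. The TCA cycle lay below 0 in 37 of 46 loci (median -0.18; both livers below in 19), with IDH3A (-0.74, SE 0.18), MDH1 (-0.64), dlst (-0.62) and suclg1 (-0.51). Amino acid breakdown lay below 0 in 32 of 41 loci (median -0.18; both livers below in 16). Its member mat1a, which makes the methyl donor S-adenosylmethionine, went from 355 ± 54.7 to 177 ± 18.5 CPM (SD, n = 2; log2 fold change -1.0, SE 0.16, edgeR adjusted p = 0.167, DESeq2 adjusted p = 2.07e-04). It was the 1 locus that passed adjusted over the list alone. oat, cbsa and aldh4a1 had log2 fold changes of -0.83, -1.11 and -0.60. Chance gives 16.7% for each of these counts of livers. Camera called oxidative phosphorylation (adjusted p = 3.79e-07; adjusted p = 0.544 with an estimated correlation), the TCA cycle (1.60e-04; adjusted p = 0.544 with an estimated correlation) and amino acid breakdown (2.76e-04; adjusted p = 0.544 with an estimated correlation). Over all genes edgeR called 0 loci of these lists, with 12, 7 and 7 lower at an unadjusted p under 0.05, and adjusted over the list alone it called 0, 0 and 1. The TCA cycle call was lost without 6 °C liver 4 (adjusted p = 0.111), and that of amino acid breakdown within cluster 1 alone (median -0.10, adjusted p = 0.0839).

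Protein synthesis transcripts were also lower at 8 than at 6 °C. Ribosomal proteins lay below 0 in 66 of 75 loci (median log2 fold change -0.20), with rplp1 (-0.83, SE 0.25), RPS13 (-0.68), RPL5 (ENSSSAG00000069558, -0.68) and rpl10 (-0.39). Both 8 °C livers lay below both 6 °C livers in 29. Translation and ribosome biogenesis lay below 0 in 29 of 36 loci (median -0.25), with eif4eb at 32.7 ± 7.38 and 17.6 ± 1.85 CPM (SD, n = 2; log2 fold change -0.90, SE 0.22) and the ribosome assembly factors nolc1 (-0.83), rrp12 (-0.74) and wdr43 (-0.51). Both 8 °C livers lay below in 17 (chance 16.7%). Camera called both, with adjusted p of 7.82e-06 and 1.53e-05 (adjusted p = 0.633 with an estimated correlation for each). Adjusted over the list alone edgeR called 0 loci in either, as over all genes, with 10 and 10 lower at an unadjusted p under 0.05, and DESeq2 called none of the named members. The ribosomal call was lost without 6 °C liver 4 (adjusted p = 0.124). Within cluster 1 alone the ribosomal median was -0.35.

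Lipogenic, glycolytic and antiviral lists also passed camera at 8 against 6 °C, but not with an estimated correlation (adjusted p = 0.816, 0.633 and 0.544). Each was lost without 6 °C liver 4, and within cluster 1 alone (adjusted p = 0.448, 0.202 and 0.326). Fatty acid synthesis lay below 0 in 21 of 27 loci (median log2 fold change -0.33), led by fasn, the fatty acid synthase, which stood at 942 CPM in 6 °C liver 4, 221 in 6 °C liver 5, and 152 and 143 at 8 °C (log2 fold change -1.98, SE 0.55, edgeR adjusted p = 0.544, and 0.0329 without 6 °C liver 5). Both named loci of the elongase elovl6 were lower (ENSSSAG00000073055, -1.35, SE 0.44; ENSSSAG00000074658, -1.13, SE 0.42) and the triglyceride-forming enzyme dgat2 was higher (0.53). Without 6 °C liver 4, the liver rich in cluster 2, the list median turned to 0.16 (adjusted p = 0.703), and without 8 °C liver 4 the adjusted p was 0.0988. Glycolysis lay below 0 in 13 of 18 loci (median -0.28), with pfkla (-0.50, SE 0.17), tpi1a (-0.80), pfkfb3 (-1.07) and eno1a (-0.28). The glycolysis call was lost without 6 °C liver 4 (adjusted p = 0.403) or 8 °C liver 5 (0.0890). The antiviral list lay above 0 in 10 of 12 loci (median 0.29), with irf1-2 (1.08, SE 0.34), irf1 (1.43, SE 0.81, and -0.05 without 8 °C liver 5), stat1a (ENSSSAG00000102446, 0.52) and dhx58 (0.79). Its call was lost without 6 °C liver 4 (adjusted p = 0.137) or 8 °C liver 5 (0.119). Camera adjusted p with the preset correlation were 0.0336 for fatty acid synthesis, 0.0381 for glycolysis and 0.0201 for the antiviral list. Both livers lay apart in the direction of the median in 7, 5 and 3 loci (chance 16.7%). Adjusted over the list alone edgeR called 0 loci in each, as over all genes, with 6 and 2 lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called none of the named members.

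Over all genes at 8 against 6 °C, edgeR called 4 of 26453 (2 higher, 2 lower), none with a symbol. At an unadjusted p under 0.05 there were 1985, and DESeq2 called 86 (29 higher, 57 lower). ENSSSAG00000084894 rose to 1274 ± 119 CPM from 166 ± 38.2 (SD, n = 2; log2 fold change 2.94, SE 0.30, edgeR adjusted p = 0.0322). ENSSSAG00000122006 fell from 146 ± 21.5 to 20.4 ± 1.59 CPM (log2 fold change -2.84, SE 0.18, edgeR adjusted p = 0.00298), and ENSSSAG00000006012 fell from 212 ± 7.63 to 70.2 ± 5.27 CPM (-1.59, SE 0.16, edgeR adjusted p = 0.0322). The edgeR count was 1 without 6 °C liver 4, 1 without 8 °C liver 4, 11 without 6 °C liver 5, and 7 without 4 °C liver 4 or 4 °C liver 5. ENSSSAG00000084894 was lost without 6 °C liver 4 (adjusted p = 0.102), 6 °C liver 5 (0.0739) or 8 °C liver 4 (0.114). ENSSSAG00000006012 was lost without 6 °C liver 4 (0.102), 6 °C liver 5 (0.0530), 8 °C liver 4 (0.133) or 8 °C liver 5 (0.106). The cholesterol synthesis list did not pass at this step (median 0.03, adjusted p = 0.944), and the lowest adjusted p in fry was 0.333.

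**Figure D3:**
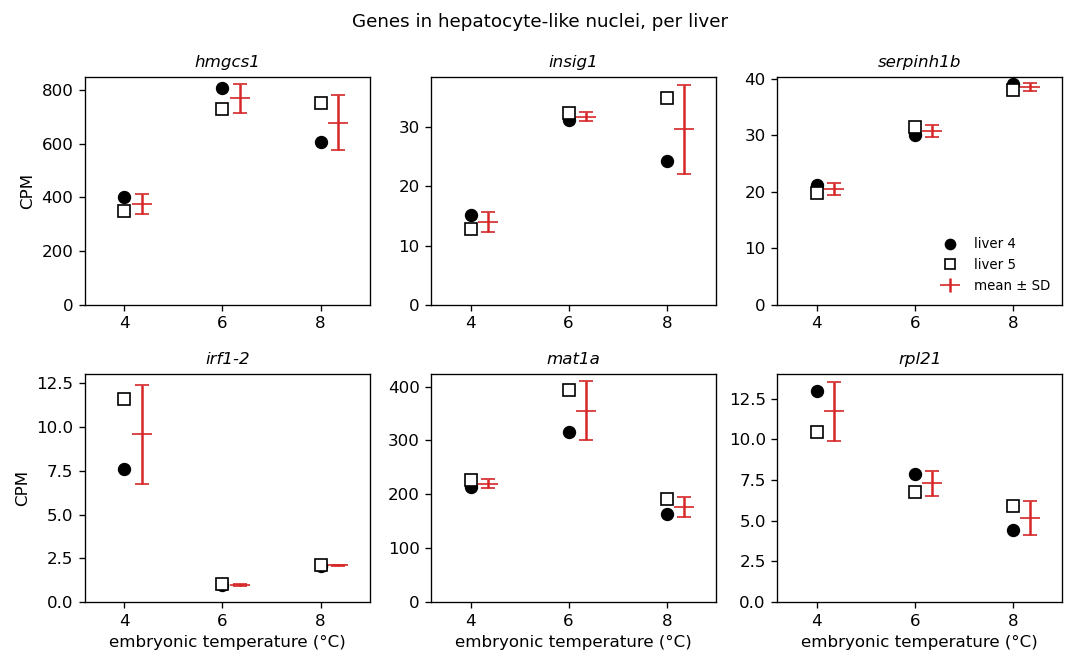
Level (CPM) of 6 named genes in hepatocyte-like nuclei against embryonic temperature (°C), 1 point per liver with the mean ± SD of each temperature. hmgcs1 and insig1 are low in both 4 °C livers, serpinh1b goes from 20.5 at 4 °C to 38.5 at 8 °C, irf1-2 is high at 4 °C, mat1a is highest at 6 °C and rpl21 goes from 11.7 to 5.17.

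Asked as 1 question over the 3 temperatures, edgeR called 7 of 26453 genes, with irf1-2 the only one that has a symbol (edgeR adjusted p = 0.0242). Of the genes, 1951 had an unadjusted p under 0.05, and DESeq2 called 201. Counts without 1 liver were above 1.5 times this without 4 °C liver 5 (13), 6 °C liver 5 (27), 8 °C liver 4 (24) and 8 °C liver 5 (21). With livers paired across temperatures instead, the same test of any difference called at most 5 genes, against 7. The pairing with 5 joined the 4 and 6 °C livers by number and kept the 8 °C livers together. Of the 29 lists, 17 passed camera in none of the 3 comparisons, with a lowest adjusted p of 0.107.

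The other cell classes were compared between 8 and 4 °C to see which differences reached beyond non-cycling hepatocytes. In cycling hepatocyte-like nuclei, both named loci of lpin1, a phosphatidate phosphatase of lipid synthesis that also acts as a transcriptional coactivator, fell (ENSSSAG00000057291, from 308 ± 31.6 to 83.6 ± 6.87 CPM, SD, n = 2, log2 fold change -1.88, SE 0.17, edgeR adjusted p = 0.00313; ENSSSAG00000055167, -3.37, SE 0.44, edgeR adjusted p = 0.0405). The bile acid synthesis enzyme hsd3b7 fell from 90.4 ± 1.80 to 31.9 ± 6.09 CPM (log2 fold change -1.50, SE 0.21, edgeR adjusted p = 0.0494), a call lost without 4 °C liver 4 (adjusted p = 0.35), 4 °C liver 5 (0.191) or 8 °C liver 4 (0.0625). The erythroid-like class does not stand apart from hepatocytes, since 485 of its 581 nuclei were hepatocyte-like at the finer clustering (median 8894 UMIs, against 1478.5 in the remaining 96). In it hmgcs1 rose from 286 ± 0.5 to 697 ± 101 CPM (SD, n = 2; 1.28, SE 0.21, edgeR adjusted p = 0.0485) and igfbp2a, which binds insulin-like growth factors, rose by 1.34 (SE 0.21, edgeR adjusted p = 0.0388). The thyroid hormone transporter slco1c1 fell from 353 ± 16.3 to 96.6 ± 5.90 CPM (-1.87, SE 0.24, edgeR adjusted p = 0.00629), as did lpin1 (-3.91, SE 0.50, edgeR adjusted p = 0.00629). The hmgcs1 call was lost without 4 °C liver 4 (adjusted p = 0.159), 4 °C liver 5 (0.165) or 8 °C liver 5 (0.132), and that of igfbp2a without 4 °C liver 5 (0.155). Hepatocyte markers in this class were at 89.2% of their level in hepatocyte-like nuclei.

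The unconventional myosin myo3a fell in cholangiocyte-like nuclei, from 96.6 ± 15.4 to 13.5 ± 3.69 CPM (SD, n = 2; log2 fold change -2.82, SE 0.36, edgeR adjusted p = 0.0301), and in immune-like nuclei (-2.92, SE 0.48, edgeR adjusted p = 0.0424). Hepatocyte markers were at 48.2% and 71.8% of their hepatocyte-like level in these classes, and myo3a was also lower in hepatocyte-like nuclei (-2.63, edgeR adjusted p = 0.228). Its cholangiocyte-like call was lost without 4 °C liver 4 (adjusted p = 0.210), 4 °C liver 5 (0.682) or 8 °C liver 5 (0.242), and its immune-like call without 4 °C liver 4 (0.167), 8 °C liver 4 (0.0700) or 8 °C liver 5 (0.397). Unnamed loci that passed included ENSSSAG00000084894 in cholangiocyte-like nuclei (2.97, edgeR adjusted p = 0.0234) and in cycling nuclei (2.58, 0.00313), and ENSSSAG00000085318 in cycling (3.96, 0.00384), erythroid-like (3.02, 0.0242) and immune-like nuclei (5.18, 0.0119). The first was lost in cholangiocyte-like nuclei without 4 °C liver 4 (adjusted p = 0.153) or 4 °C liver 5 (0.859), and the second in erythroid-like nuclei without 4 °C liver 4 (0.108).

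In all, edgeR called 3 genes in cholangiocyte-like nuclei (2 higher, 1 lower; 819 at an unadjusted p under 0.05; DESeq2 8), 7 in cycling hepatocyte-like nuclei (4 and 3; 1336; DESeq2 39), 9 in erythroid-like nuclei (7 and 2; 719; DESeq2 12) and 7 in immune-like nuclei (5 and 2; 719; DESeq2 10). It called 0 in endothelial-like nuclei (235 at an unadjusted p under 0.05; DESeq2 0) and 0 in mesenchymal-like nuclei (599; DESeq2 7), where sums per liver were as low as 150855 and 303938 UMIs. Without 8 °C liver 4 the counts were 45 in cholangiocyte-like, 46 in cycling, 60 in endothelial-like, 20 in erythroid-like and 14 in immune-like nuclei, and without 8 °C liver 5 they were 4, 22, 16, 16 and 7. Without 4 °C liver 4 they were 0, 5, 0, 12 and 11, without 4 °C liver 5 0, 9, 0, 9 and 29, without 6 °C liver 4 6, 14, 0, 12 and 16, and without 6 °C liver 5 6, 17, 0, 24 and 20. The thrombocyte-like class had too few nuclei to test.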

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

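The tests of explanations for the cholesterol, ribosomal and endothelial patterns were chosen after the results were seen.

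Pancreatic acinar-like nuclei, a class that the comparisons do not use, appeared at the finer clustering (resolution 1.0) with 7 of 7 informative markers detected, led by the digestive enzyme genes CEL, cpb1 and ctrl. They numbered 22 in 8 °C liver 5 (0.881% of its nuclei), 8 in 6 °C liver 4 (0.181%) and 5 in 6 °C liver 5 (0.194%), above the limit of 3 that a count of 0 allows. In 4 °C liver 4, 4 °C liver 5 and 8 °C liver 4 they numbered 0, 1 and 1. The limit takes no account of the nuclei kept, 4426 and 2573 in the 6 °C livers and 1933 in 4 °C liver 4. The 6 °C counts are therefore not read as a difference. Of the 37 nuclei, 34 had been placed with cholangiocyte-like and 3 with hepatocyte-like nuclei at the coarser clustering.

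Cholesterol synthesis transcripts lay lower in both 4 °C livers than in all others. If a different make-up of hepatocyte clusters were the whole cause, the difference would shrink within 1 cluster; within cluster 1 the list's mean level, here log2(CPM + 0.5) without TMM scaling, was 0.62 higher at 8 than at 4 °C (SD between livers of a temperature 0.18), against 0.55 (SD 0.15) over all hepatocyte-like nuclei, which argues against it (with TMM scaling, as in the figure, the means over all were 5.73 and 5.11). With the sum of every liver thinned to the shallowest total the difference was 0.54 (SD 0.16). Thinning a sum at random leaves expected CPM as they were, so this could not decide whether depth per nucleus played a part. Median UMIs per nucleus overlapped between the 4 °C (7500 and 5955) and 8 °C livers (5772 and 8714). A lasting effect of embryonic temperature on sterol synthesis stays open as an untested hypothesis, as do differences in recent feeding or handling between these few samples. The test over the list did not pass with an estimated correlation, so the pattern itself is also not settled.

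Ribosomal protein transcripts lay lower at higher temperature. If warmer livers simply carried less cytoplasm with their nuclei, oxidative phosphorylation transcripts, also short and cytoplasmic, would be lower too. Between 6 and 4 °C their mean log2(CPM + 0.5) without TMM scaling differed by 0.10 (SD 0.09), while the ribosomal level differed by -0.29 (SD 0.12). These values argue against an equal fall of both lists at that step (with TMM scaling the means were 2.66 and 2.46, and 2.79 and 3.02). The oxidative phosphorylation level was 2.64 and 2.62 in the 4 °C livers, and 2.82 and 2.65 in 6 °C livers 4 and 5. Most of the rise thus lay in 6 °C liver 4. That list was itself called higher at 6 °C, and a rise of its own could hide less cytoplasm. The test therefore cannot decide for this step. Within cluster 1 alone the ribosomal median log2 fold change at this step was only -0.09. At 8 against 6 °C both lists were lower, with medians of -0.28 for oxidative phosphorylation (49 of 56 loci below 0) and -0.20 for ribosomal proteins (66 of 75). Within cluster 1 these medians were -0.36 and -0.35. Less cytoplasm would give this too, so it stays open for the upper step as well. Mean levels of both lists were also lower at 8 than at 4 °C (-0.15, SD 0.05, and -0.45, SD 0.06). Free RNA shared by all nuclei of a liver would lower the list in every class; its median log2 fold change at 8 against 4 °C was 0.085 in endothelial-like, -0.13 in cholangiocyte-like, -0.19 in mesenchymal-like and -0.44 in immune-like nuclei, and -0.67 in erythroid-like nuclei, which the test leaves out because they carry most hepatocyte transcripts. The classes disagree, and the endothelial-like value rests on 8 loci and on 25 and 37 nuclei at 4 °C. Free RNA, less cytoplasm at higher temperature and a difference within hepatocytes therefore cannot be told apart here. A lasting difference in protein synthesis with embryonic temperature stays open as an untested hypothesis.

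Endothelial-like nuclei took a larger share at higher temperature. A lower share of hepatocytes would raise all other classes alike; endothelial-like nuclei per 100 cholangiocyte-like, immune-like and mesenchymal-like nuclei were instead 14.8 and 14.7 at 4 °C, 24.1 and 26.5 at 6 °C, and 36.8 and 33.8 at 8 °C, a difference of 20.6 between 8 and 4 °C (SD 1.51), which argues against it. Slopes were 0.552 and 0.643 percentage points per °C in libraries 1 and 2 taken alone. Both libraries held nuclei of every liver in similar proportions, as with 1050 and 883 in 4 °C liver 4 and 1349 and 1149 in 8 °C liver 5. A difference between libraries was thus balanced over temperature, and the similar slopes decide nothing further. A difference between livers in how well endothelial nuclei were released or kept was not tested and stays open. A lasting effect of embryonic temperature on liver vessels stays open as an untested hypothesis.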

How the results depend on the processing

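Scrublet's automatic doublet threshold, the addition of the cycling cluster and the use of cluster 1 alone were alternatives chosen after seeing the data; the others were planned, and unless stated the cause of a change was not tested. Counts of genes are for edgeR in hepatocyte-like nuclei at 8 against 4 °C, 6 against 4 °C, 8 against 6 °C and any difference, where the main counts were 6, 2, 4 and 7. Calls of single genes therefore depend on the tool and filter: DESeq2 gave 106, 95, 86 and 201, and no filter on low counts gave 568, 624, 579 and 1173. Without a filter 49625 genes were tested in place of 26453, and edgeR pooled the spread fully across genes, against 5.75 prior degrees of freedom with the filter. Of the 568 called at 8 against 4 °C, 542 were also tested with the filter, where 6 genes passed. This argues against the added genes as the source of most of these calls. The full pooling was not tested apart from other changes that dropping the filter brings. The stricter filter left 11657 genes and calls of 0 (928 at an unadjusted p under 0.05), 0 (849), 1 and 1. Sums over all nuclei gave 0 (2366 unadjusted) at 8 against 4 °C, 0 (1963) at 6 against 4 °C and 2 at 8 against 6 °C. A straight line in temperature gave 2 for 8 against 4 °C and 2 for any difference. At least 400 genes per nucleus gave 16 at 8 against 4 °C, and no doublet removal also 16. Library 1 alone gave 11, 0 (1507 unadjusted), 7 and 15, and sums thinned to the shallowest liver gave 19 at 8 against 4 °C, 1 at 6 against 4 °C and 14 for any difference. At 6 against 4 °C only the 4 livers compared gave 12, and the count was 0 with 400 genes (1743 unadjusted), no doublet removal (1734), resolution 1.0 (1839), the automatic doublet threshold (1738), the cycling cluster added (1861), cluster 1 alone (1383) and limma-voom (1798). At 8 against 6 °C the cycling cluster added and cluster 1 alone each gave 7, and limma-voom gave 3 for any difference.

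Lists called at 8 against 4 °C, 6 against 4 °C and 8 against 6 °C (4, 7 and 8 with the preset correlation) numbered 0, 0 and 0 with an estimated correlation (1, 2 and 1 at an unadjusted p under 0.05) and 0, 0 and 0 in fry for 1 direction (4, 3 and 2 unadjusted). In fry for either direction they numbered 4, 2 and 0 (2 unadjusted at 8 against 6 °C). Those at 8 against 4 °C were other lists than camera's, bile acids, antiviral response, thyroid and nuclear receptors (adjusted p = 0.0152 each) and glycogen metabolism (0.0157), while cholesterol synthesis had 0.0597, ribosomal proteins 0.0615, heat shock 0.319 and translation 0.492. At 6 against 4 °C they were antiviral response (0.0167) and thyroid and nuclear receptors (0.0449). The cycling cluster added gave 8 at 8 against 4 °C, cluster 1 alone gave 2 there and 4 at 8 against 6 °C, and the stricter filter gave 5 at 8 against 6 °C. The fatty acid synthesis median at 8 against 6 °C turned to 0.12 in cluster 1 alone and to 0.16 without 6 °C liver 4, the end of a range from -0.33. elovl6 (ENSSSAG00000073055) turned to 0.32 in cluster 1 alone, which leaves out the lipogenic cluster 2. Over the called lists, 114 of 188 values under alternatives other than leaving out a liver kept direction and call, 73 kept direction only and 1 reversed. Over the 82 single-gene results followed in hepatocyte-like nuclei, 1315 of 1385 kept both, 37 gained a call, 32 lost one and 1 reversed. Most of these results had not passed in the main fit, so keeping the call mostly meant staying uncalled. Only the few that had passed could lose a call. In other classes, where every named gene had passed, 52 of 54 kept both and 2 lost the call.

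In other classes at 8 against 4 °C, DESeq2 gave 8 in cholangiocyte-like, 39 in cycling and 7 in mesenchymal-like nuclei, 76 in all classes together against 26. No filter gave 179 in cholangiocyte-like, 263 in cycling, 7 in endothelial-like, 80 in erythroid-like, 101 in immune-like and 32 in mesenchymal-like nuclei, 662 together. The slope of the immune-like share turned to 0.0182 in library 1 and that of the mesenchymal-like share to -0.0984 in library 2. An edgeR test on numbers of nuclei called 1 class, endothelial-like, at 0.31 on the log2 scale per °C; slopes of that share under the other alternatives were 0.552 to 0.668.

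With 1 liver left out, the lone liver of its temperature is assumed to vary like the others. For single genes in hepatocyte-like nuclei, keeping the call again mostly means staying uncalled. Only the few that passed in the main fit could lose a call. Counts of genes ranged over 0 to 17, 0 to 13, 1 to 11 and 9 to 27 in hepatocyte-like nuclei, and counts of lists over 3 to 6, 6 to 9 and 5 to 10, with 5 without 6 °C liver 4. In other classes counts ranged over 0 to 45 in cholangiocyte-like, 5 to 46 in cycling, 0 to 60 in endothelial-like, 9 to 24 in erythroid-like, 7 to 29 in immune-like and 0 to 2 in mesenchymal-like nuclei, and over 30 to 187 together. Share slopes ranged over -0.383 to 0.520 for cholangiocyte-like, 0.376 to 2.15 for cycling, 0.503 to 0.697 for endothelial-like, -0.862 to -0.280 for erythroid-like, -1.89 to -0.498 for hepatocyte-like, -0.248 to -0.0696 for immune-like, -0.231 to 0.207 for mesenchymal-like and 0.0216 to 0.0560 for thrombocyte-like nuclei; the mesenchymal-like slope was -0.156 without 4 °C liver 4. Slopes of median UMIs ranged over -122 to 509 (-101 without 4 °C liver 5), of median genes over -60.1 to 124 (-41.8 without 4 °C liver 5) and of genes at 2000 UMIs over -7.14 to -2.71. Of the called lists' values 93 of 114 kept direction and call, 20 lost the call and 1 reversed. Of the values of these single-gene results 471 of 492 kept both, 19 lost the call, 1 gained it and 1 reversed, irf1 at 8 against 6 °C, at -0.0545 without 8 °C liver 5, in a range up to 2.33; in other classes 85 of 108 kept both and 23 lost the call.

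The numbers 4 and 5 in the codes were not taken as a pairing, since deviations of same-numbered livers from their temperature means correlated at only 0.0808, 0.0477 and 0.117. Principal component 2 (21.8% of variance) nevertheless parted the numbers, at 42.1, 18.6 and 14.6 for liver 4 and -17.7, -22.5 and -35.2 for liver 5 from 4 to 8 °C, so something shared by number is not excluded. With the number as a block the counts were 22, 14, 14 and 24 in hepatocyte-like nuclei, 6 in cholangiocyte-like and 12 in cycling nuclei, and irf1 at 6 against 4 °C gained a call; no other named gene or list call changed. Depth limits which transcripts could be tested: with endothelial-like sums down to 150855 UMIs per liver the same filter left 9177 genes there, against 26453 in hepatocyte-like nuclei. The spread between livers was also widest there (biological coefficient of variation 0.382, against 0.169 to 0.252 in the other smaller classes), and which of these limits the calls was not tested.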

Other observations

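The genes named in this part were chosen after their values were seen, as were the trends of lists over temperature; the gene lists themselves were fixed before.

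Single loci of thyroid hormone handling and bile acid synthesis stood apart in hepatocyte-like nuclei, while their lists went both ways at 8 against 4 °C (32 loci above and 28 below 0, and 7 and 7). Camera called neither list (adjusted p = 0.822 and 0.855). Fry for either direction called both (adjusted p = 0.0152 each). Both loci of dio2, the deiodinase that activates thyroid hormone, lay lower at 8 than at 4 °C. ENSSSAG00000003055 stood at 77.0 ± 18.1 CPM (SD, n = 2) at 4 °C, 33.2 ± 3.63 at 6 °C and 21.7 ± 3.61 at 8 °C (log2 fold change -1.82, SE 0.22, edgeR adjusted p = 0.0506). ENSSSAG00000064521 stood at 60.6 ± 3.30, 21.4 ± 1.76 and 14.3 ± 7.07 CPM (-2.09, SE 0.30, edgeR adjusted p = 0.0872). Within cluster 1 alone the first was at 64.4 ± 44.3 CPM at 4 °C and 21.4 ± 5.14 at 8 °C, and the second at 53.0 ± 5.44 and 12.5 ± 6.48. dio2 is also a leading gene of cluster 5, which was mostly made of 4 °C nuclei. The thyroid hormone receptor thrb had a log2 fold change of -0.64 (SE 0.14, edgeR adjusted p = 0.368). These 3 loci passed adjusted over the list alone (60 loci), against 0 over all genes in edgeR. The bile acid enzyme hsd3b7 stood at 129 ± 2.55 CPM at 4 °C, 121 ± 6.93 at 6 °C and 53.2 ± 9.02 at 8 °C (log2 fold change -1.28 against 4 °C, SE 0.17, edgeR adjusted p = 0.0567) and was the 1 of 14 loci that passed adjusted over its list alone. The lipid regulator lpin1 (ENSSSAG00000055167) stood at 295 ± 211 CPM at 4 °C against 31.9 ± 4.98 at 8 °C (edgeR adjusted p = 0.0810). Within cluster 1 lpin1 was at 51.1 and 30.1 CPM. It also leads cluster 5, and the cause was not tested.

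Single growth factor transcripts went both ways. The growth hormone and insulin-like growth factor list had 23 of 38 loci above 0 and 15 below at 8 against 4 °C. Camera did not call it (adjusted p = 0.693). The binding protein igfbp2a (ENSSSAG00000096998) stood at 1562 ± 153 CPM (SD, n = 2) at 4 °C, 2611 ± 870 at 6 °C and 3871.5 ± 680 at 8 °C, while the growth factor igf2b stood at 264 ± 6.93, 238 ± 0.566 and 148 ± 20.5. Log2 fold changes at 8 against 4 °C were 1.31 and -0.84 (edgeR adjusted p = 0.211 for both). These 2 loci passed adjusted over the growth hormone list alone. At 6 °C 3 further transcripts were at their highest. fkbp5 at 107 ± 31.4, 173 ± 30.4 and 52.8 ± 5.65 CPM from 4 to 8 °C, tsc22d3 at 18.7 ± 0.141, 32.7 ± 0.403 and 12.6 ± 1.75, and the clock gene nfil3-6 at 14.3 ± 1.16, 24.1 ± 3.34 and 7.86 ± 0.688. Their log2 fold changes at 8 against 6 °C were -1.71, -1.37 and -1.62 (edgeR adjusted p = 0.110, 0.0748 and 0.0677). IGFBP1 was highest at 6 °C too, at 130 ± 1.06 CPM against 43.9 at 4 °C (1.57, edgeR adjusted p = 0.264).

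The lists that passed camera in none of the comparisons had small medians at 8 against 4 °C. On the log2 scale these were 0.16 for polyunsaturated fatty acid synthesis, 0.08 for hypoxia, 0.07 for endoplasmic reticulum stress, 0.07 for the growth hormone and insulin-like growth factor axis, 0.06 for the circadian clock, 0.06 for iron and haem, 0.05 for bile acids, 0.03 for thyroid and nuclear receptors, 0.02 for xenobiotic metabolism, 0.02 for protein breakdown and 0.01 for gluconeogenesis. Medians were -0.01 for antioxidant genes, -0.03 for fatty acid oxidation, -0.05 for insulin and TOR signalling, -0.05 for complement and acute phase proteins, -0.05 for DNA methylation and chromatin and -0.12 for the cell cycle, with adjusted p from 0.122 to 0.944. Cholesterol synthesis had medians of 0.82 in cycling hepatocyte-like, 0.72 in erythroid-like, 0.58 in immune-like, 0.34 in cholangiocyte-like, 0.34 in mesenchymal-like and -0.15 in endothelial-like nuclei at 8 against 4 °C, in classes that also carry hepatocyte transcripts. These values, and the calls that follow, are from camera with the preset correlation; no test with an estimated correlation was made in these classes, and in hepatocyte-like nuclei that test called 0 lists in each comparison (camera; 1, 2 and 1 at an unadjusted p under 0.05; fry for 1 direction 0). Of 17 lists called in cholangiocyte-like nuclei 14 were lower, among them amino acid breakdown (median -0.47, adjusted p = 6.38e-06) and complement and acute phase proteins (-0.43, adjusted p = 1.56e-05), and all 8 called in endothelial-like nuclei were lower, among them amino acid breakdown (-0.48, adjusted p = 1.04e-04) and the TCA cycle (-0.54, adjusted p = 0.00105). These lists are active in hepatocytes, and RNA carried over from hepatocytes was not separated from the classes' own. The cholangiocyte-like class also holds 34 of the 37 acinar-like nuclei, of which 22 came from 8 °C liver 5 and 0 and 1 from the 4 °C livers, so its make-up differed between the groups. As a trend over the 6 livers, ribosomal protein levels changed by -0.11 on the log2 scale per °C and polyunsaturated fatty acid synthesis by 0.03, both at the smallest exact permutation p, 0.0222 (0.322 adjusted over 29 lists).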
